A study of Homo sapiens with 3 samples.

How the data were processed

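RNA of 3 cultures was analysed, 1 array per culture: parental HME1 cells, HME1 with HRasG12V, and HME1 with HRasG12V and ZEB1. Per the labels' protocols, total RNA was extracted on columns, and 100 ng was amplified and labelled with biotin by a 3' in vitro transcription kit before hybridisation to an Affymetrix GeneChip. Per the submitters' processing notes, the values came from the RMA method in Affymetrix Expression Console 1.1, and the values the authors deposited are on a log2 scale, as their range of 1.53 to 14.24 on all arrays shows. RMA includes background correction, quantile normalization of the arrays against each other and a median-polish summary of each probe set, so a global difference in RNA amount between cultures cannot be seen in these values. The quantiles of the deposited columns differed by at most 0.10 between any 2 arrays. Many values were exactly equal between arrays, for a reason that was not tested: 13481 of 54675 probe sets, or 24.7%, were identical on all 3 arrays, and 53.3% on at least 2. Among the genes analysed, 8.88% to 9.69% were identical on the 2 arrays of a comparison, and these enter list medians and the noise estimate as differences of 0. No column was left unmapped, and other processing steps are not given in the sources used here.

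Probe sets were named from the platform annotation that was supplied. A single gene symbol was listed for 41097 probe sets, several for 1801, and 11777 were not listed and are unnamed here. Of 62 control probe sets, 6 were listed with ACTB or GAPDH, and 0 genes were represented by one. Entrez identifiers of 41043 probe sets matched a RefSeq gene table of the current human reference assembly, and 0 symbols needed an update from it. That table served only for names and for the order of neighbouring genes, and no coordinate is printed. Probe sets of sex-linked marker genes, 59 in number, were left out. Probe sets without a single gene name entered no gene result. The remaining probe sets covered 19740 genes. Each gene was represented by the probe set with the highest mean over the 3 arrays, and kept where the highest of the 3 log2 values was at least 6, which left 11076 genes.

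There were 3 comparisons, each a difference of log2 values: RAS minus parental, ZEB1-RAS minus RAS and ZEB1-RAS minus parental. With 1 array per group there was no test, SE or SD between cultures, and the number of arrays limits the precision. Genes were counted by a size rule of 2-fold in either direction. A fold is 2 to the power of the size of the log2 difference. The noise of a difference was estimated as the robust SD (1.4826 times the median absolute deviation) of the disagreement between the 2 probe sets of a gene, divided by the square root of 2. It measures disagreement within the same arrays, not between cultures. The 42 bacterial control probe sets had median differences of −0.15, 0.06 and −0.09 in the 3 comparisons.

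The 19 gene lists were fixed before the data were examined: epithelial junction and identity, mesenchymal and matrix, basal mammary, luminal mammary, keratinocyte differentiation, MAPK pathway output, senescence-associated secretory, DNA replication, mitosis, DNA damage response and repair, p53 targets, cell cycle inhibitors, antioxidant and methionine sulfoxide reductase, stem cell associated, interferon-stimulated, glycolysis and hypoxia, cholesterol synthesis, leukocyte and endothelial, and ribosomal protein. For each, the median difference of its measured genes was set against 10000 random lists of the same size, drawn within 20 bins of mean expression. This percentile describes these arrays and is not a p-value. The genes named were also picked by a rule fixed before the data were examined, which selects most of them by the size of their differences. They are ZEB1 and HRAS, the 12 highest and 12 lowest differences per comparison among genes whose passing probe sets share a sign and whose main probe set is not of the _x_at kind, up to 4 members per list and comparison with the largest differences of at least 2-fold (or up to 2 where none reached it), and MSRB3, CDH1, VIM and CDKN1A. Main probe sets of the _x_at kind, which is prone to cross-hybridisation, read the list members CXCL5, CDH11, DCN, CD24, CA12, IDI1 and PTTG1 in every comparison. The text says where a gene outside this rule was named after its value was seen.

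The differences of RAS and ZEB1-RAS from the shared parental array were compared by counts of genes, by the overlap that independent lists would have, and by their covariance beside 100 simulated sets of unchanged arrays. Windows of at least 50 neighbouring measured genes were formed along each chromosome over 11059 placed genes. Their medians were compared with the 99th percentile of the most extreme window in 1000 shuffles of gene order, and a window was counted as a shift of a segment where at least 80% of its genes also shared a sign.

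The scripts were tested on simulated arrays with a spread of 0.11 log2 units. That spread comes from probe sets within arrays and leaves out differences between cultures, so the simulation gives no rate of false calls for these cultures. In the simulated RAS minus parental comparison over 10785 genes, 100% of 50 genes shifted by 1.5 log2 units and 58% of 50 genes shifted by exactly 1 passed the 2-fold rule, as did 0 of 10585 unshifted genes. In the simulated ZEB1-RAS minus parental comparison, with 202 windows in all, both windows on a raised segment were found and 0 elsewhere were counted. The alternatives fixed before the data were examined were the median over a gene's probe sets, only probe sets without a shared-sequence suffix, no filter, a filter at 7, equal array medians, a loess trend (span 0.3) removed, 32 added to the linear intensity, and size rules of 3-fold and 1.5-fold. Alternatives chosen after the data were seen left out genes of windows beyond the shuffled limit in any comparison or genes with identical values. They also applied the first 7 settings to the window counts and to turning genes. Turning genes are those with 2-fold differences of opposite sign in RAS minus parental and ZEB1-RAS minus RAS. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.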

Results

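Genome-wide RNA levels were measured in 3 cultures of human mammary epithelial cells that telomerase had made immortal, a line of non-cancerous breast origin called HME1. The first culture was the parental line. The second had received a retrovirus carrying HRasG12V, a permanently active form of the small GTPase HRAS, and its label calls it non-transformed; it is called RAS here. The third had received HRasG12V together with ZEB1, a zinc-finger repressor that drives the epithelial-mesenchymal transition, and its label calls it transformed; it is called ZEB1-RAS here. The series title places these arrays in a study of ZEB1, DNA replication stress and chromosomal instability in cancer stem cells. Each culture was hybridised to 1 array, so no value below has a replicate, no p-value was computed, and every difference is between these 3 arrays rather than between conditions. Each array held log2 values of 54675 probe sets, with medians of 5.17 for parental, 5.17 for RAS and 5.15 for ZEB1-RAS. The spread used was the disagreement between 2 probe sets of the same gene, an SD of 0.16 log2 units for RAS minus parental, 0.16 for ZEB1-RAS minus RAS and 0.14 for ZEB1-RAS minus parental over 2956 genes. It is not a spread between cultures; differences of 42 bacterial control probe sets ranged from −0.55 to 0.02, −0.02 to 0.38 and −0.21 to 0.02 in these comparisons. The 3'-minus-5' difference of GAPDH, a sign of RNA integrity, was 0.28, 0.32 and 0.20 on the parental, RAS and ZEB1-RAS arrays, and that of ACTB was 2.07, 1.95 and 1.92. A gene was represented by its brightest probe set and kept where the highest of the 3 log2 values was 6 or more, which left 11076 genes. Where the lower of 2 values lies far below the array median, the size of the fold difference is uncertain.

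The introduced genes were examined first. ZEB1 was seen on the ZEB1-RAS array by probe set 212764_at, at 7.66 against 2.09 on the parental and 2.27 on the RAS array, a 41.8-fold higher value than with RAS alone. The other 3 ZEB1 probe sets stayed under a log2 value of 5 on every array, and 210875_s_at among them was 2.76-fold higher on the ZEB1-RAS array than on the RAS array. Since the ZEB1 probe set with the highest mean, 212758_s_at, missed the filter, ZEB1 does not enter the gene counts. HRAS had 1 probe set, 212983_at, which read 9.73, 9.95 and 10.76 on the parental, RAS and ZEB1-RAS arrays. It was thus 1.17-fold higher with RAS and 2.04-fold higher with ZEB1-RAS than in parental cells; whether this probe set lies inside the retroviral insert was not analysed here, so it does not check the label. MSRB3, a methionine sulfoxide reductase that repairs oxidised protein, was higher in the order parental, RAS, ZEB1-RAS on each of its 5 probe sets; the brightest, 225782_at, read 7.90, 8.63 and 10.14.

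**Figure D1:**
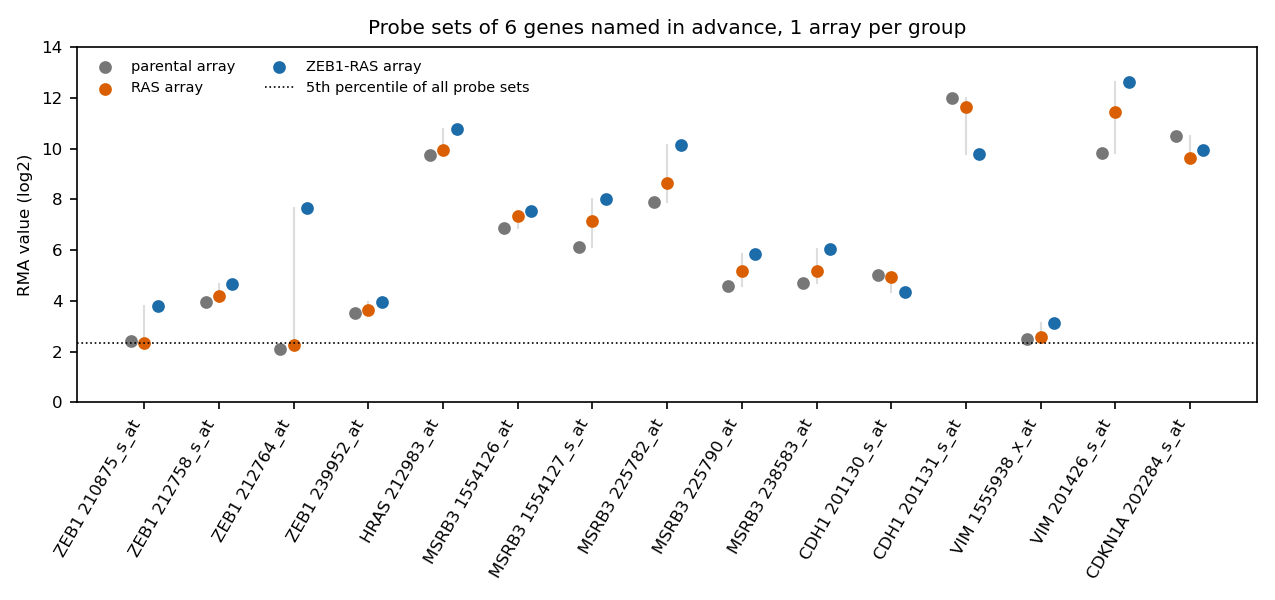
RMA values (log2, vertical axis) of every probe set of ZEB1, HRAS, MSRB3, CDH1, VIM and CDKN1A on the parental, RAS and ZEB1-RAS arrays, 1 point per array. The ZEB1 probe set 212764_at stands at 7.66 on the ZEB1-RAS array against 2.27 on the RAS array, and all 5 MSRB3 probe sets are lowest on the parental array.

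By its labels, the comparison of RAS with parental cells asks what HRasG12V alone does to these cells. On the RAS array the MAPK output, senescence-associated secretory and cholesterol synthesis lists had medians above 0, and the DNA replication, p53-target, basal and keratinocyte differentiation lists medians below 0. Of the 11076 genes, 300 were at least 2-fold higher and 483 at least 2-fold lower. Among genes whose probe sets agreed in sign and whose main probe set was not of the cross-hybridising _x_at kind, the highest differences were those of IL13RA2, a decoy receptor for interleukin 13, at 95.5-fold, the long non-coding RNA LINC00973 at 25.8-fold, the collagenase MMP1 at 16.3-fold and the adaptor GRB10 at 13.4-fold. FOXA2, a forkhead transcription factor, was 11.6-fold higher, BLMH 8.68-fold, PTPN20 8.48-fold, LAPTM5 8.11-fold, COL13A1 7.62-fold, the scaffold AKAP12 7.51-fold, PDE2A 7.30-fold and the claudin CLDN11 7.21-fold. In the other direction, the selenium carrier SELENOP was 70.2-fold lower, the chemokine receptor ACKR3 30.4-fold, complement factor I (CFI) 22.0-fold, the basement membrane linker NID1 18.8-fold and the KIT ligand KITLG 16.3-fold. EYA2, GAS1, PCSK5, PLSCR4, IRX5, ITGA4 and IGFBP3 followed, 15.2-fold to 12.7-fold lower.

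The MAPK output list, transcripts induced downstream of RAS, RAF and ERK, had a median difference of 0.45, above each of 10000 random lists matched on expression. Of its 32 measured genes, 10 were at least 2-fold higher, among them HMGA2 (3.67-fold), the ERK phosphatase DUSP6 (3.43-fold), the EGFR ligand EREG (3.06-fold) and the ETS factor ETV5 (a difference of 1.58). FOS and EGR1, the 2 members at least 2-fold lower, were named by the fixed rule for another comparison and differed by −1.22 and −1.14. The median was 0.26 when the median over a gene's probe sets was used. Senescence-associated secreted factors had a median of 0.57, also above each random list, with 9 of 26 at least 2-fold higher and 4 lower. CXCL5, a neutrophil chemokine read by a probe set of a kind prone to cross-hybridisation, was 161-fold higher, MMP1 16.3-fold and IL1B 6.73-fold, while IGFBP3 was 12.7-fold lower. The other members at least 2-fold lower were STC1, named by the fixed rule for another comparison, and IGFBP2 and IGFBP6, named after their values were seen. That median was 0.35 with the filter at 7 and 0.23 with no filter. Cholesterol synthesis had a median of 0.50 and 17 of 18 genes above 0; the squalene epoxidase SQLE was 4.19-fold higher, HMGCS1 2.76-fold, ACAT2 2.48-fold and IDI1 2.45-fold.

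DNA replication genes were lower as a group on the RAS array. Their median difference was −0.48, below each of the random lists, with 52 of 62 genes below 0, 8 at least 2-fold lower and 0 at least 2-fold higher. The epigenetic regulator UHRF1 was 3.03-fold lower, the helicase subunits MCM5 and MCM3 2.69-fold and 2.64-fold, and the ribonucleotide reductase subunit RRM2 2.23-fold. Mitosis genes did not share this: their median was 0.02 and 0 of 44 passed 2-fold, with CDC25B 1.80-fold and PTTG1 1.59-fold higher. DNA damage response and repair genes had a median of −0.03, and 3 of 50 were at least 2-fold lower: the helicase BRIP1 (2.20-fold), the nuclease EXO1 (2.08-fold) and the bypass polymerase POLH (2.03-fold). p53 targets had a median of −0.35, below each random list, with TP53I3 3.22-fold, DDB2 2.31-fold, PLK2 2.29-fold and PHLDA3 2.20-fold lower; CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, was 1.84-fold lower. Cell cycle inhibitors had a median of −0.04 over 8 genes, and CDKN2B, encoding p15, was the 1 member at least 2-fold higher (2.18-fold).

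Epithelial junction genes were balanced, with a median of 0.01; OVOL1 and EPCAM were 3.64-fold and 3.16-fold higher, and OVOL2 and CLDN1 2.35-fold and 2.14-fold lower. CDH1, or E-cadherin, was 1.28-fold lower. Mesenchymal and matrix genes had a median of −0.01, which was 0.25 with the median over a gene's probe sets, with 6 of 36 at least 2-fold higher and 5 lower. VIM, the intermediate filament vimentin, was 3.07-fold higher and the cadherin CDH11, on a probe set prone to cross-hybridisation, 31.1-fold higher, whereas the repressor ZEB2 was 9.82-fold, the gelatinase MMP2 4.72-fold and CCN2 4.65-fold lower. COL5A2 and DCN, the other members at least 2-fold lower, were named by the fixed rule for other comparisons. Basal mammary genes had a median of −0.35, at the 0.01 percentile of random lists, with MME 6.69-fold, KRT14 6.19-fold, KRT5 3.04-fold and KRT15 2.82-fold lower. Luminal genes had a median of −0.07, although GATA3, MUC1 and MYB were 5.33-fold, 4.54-fold and 2.59-fold lower. Keratinocyte differentiation genes had a median of −0.55, below each random list, with 8 of 18 at least 2-fold lower, including the kallikreins KLK5 (8.78-fold) and KLK7 (7.08-fold) and the transglutaminase TGM1 (4.79-fold); S100A7 was 3.94-fold higher. Interferon-stimulated genes had a median of −0.36, below each random list, with IFI44L 3.39-fold and IFITM1 3.15-fold lower, and SAMD9 and HERC6 2.67-fold and 2.41-fold lower. Stem cell associated genes had a median of −0.47, which was −0.03 without the filter; ALDH1A1 was 5.51-fold and NOTCH1 2.13-fold lower, and the efflux pump ABCG2 2.59-fold higher. Antioxidant genes had a median of −0.02, with GPX2 3.16-fold and HMOX1 2.05-fold higher and catalase (CAT) 2.44-fold lower. Glycolysis and hypoxia genes had a median of −0.05, with ALDOC 2.48-fold higher and ADM 2.42-fold lower. Ribosomal protein genes had a median of 0.00, with RPL34 at −0.21 and RPL30 at 0.16. Of the leukocyte and endothelial markers, 3 were measured, with a median of 0.14, and CD14 was 2.10-fold higher. The count of genes at least 2-fold lower was 293 of 8855 when the median over a gene's probe sets was used, against 483 of 11076.

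By its labels, the comparison of ZEB1-RAS with RAS asks what ZEB1 adds to HRasG12V, although the HRAS probe set was also 1.75-fold higher on the ZEB1-RAS array. On the ZEB1-RAS array the epithelial program was much lower and mesenchymal and matrix transcripts were higher, while DNA replication and mitosis genes differed little. Of 11076 genes, 508 were at least 2-fold higher and 566 at least 2-fold lower. The reticulon RTN1 was 272-fold higher, the integrin ligand EDIL3 163-fold, TMTC1 76.1-fold, SELENOP 59.6-fold, PRR16 48.5-fold, the WNT antagonist SFRP1 44.0-fold, the hyaluronan synthase HAS2 43.4-fold and GNG11 39.4-fold. CLGN, the neurofilament gene NEFL, SESN3 and NID1 followed at 36.1-fold to 25.6-fold. The chloride channel ANO1 was 152-fold lower, the adhesion molecule EPCAM 76.6-fold, the keratin KRT23 75.9-fold, the glutathione peroxidase GPX2 53.2-fold, GUCY1B1 42.3-fold, COXFA4L3 41.2-fold, the epithelial splicing factor ESRP1 34.5-fold and the tight junction protein OCLN 30.4-fold. EXPH5, KRT13, TMEM30B and SPRR1B were lower by log2 differences of −5.00, −4.92, −4.84 and −4.77.

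Epithelial junction and identity genes had a median difference of −1.64, below each of the 10000 random lists, and 30 of 43 were at least 2-fold lower, including CDH1 at 3.60-fold. The 2 members at least 2-fold higher were GRHL3 (1.27) and PKP1 (1.07), named after their values were seen. Mesenchymal and matrix genes had a median of 0.82, above each random list, with 16 of 36 at least 2-fold higher and 0 lower. The proteoglycan DCN, on a probe set prone to cross-hybridisation, was 54.9-fold higher, ZEB2 16.1-fold, the microfibril protein FBN1 12.2-fold, COL5A2 10.7-fold and VIM 2.24-fold. Luminal genes had a median of −0.59, with CLDN8 17.9-fold, CD24 10.5-fold, WFDC2 10.5-fold and ALDH1A3 5.69-fold lower. MLPH, named after its value was seen, was the 1 luminal member at least 2-fold higher. Basal genes went both ways around a median of −0.10: MME and KRT14 were 10.3-fold and 5.44-fold higher, and KRT15 and FGFBP1 6.60-fold and 4.78-fold lower. Keratinocyte differentiation genes had a median of −1.57, below each random list, with 10 of 18 at least 2-fold lower, among them KRT13, SPRR1B, LCN2 (16.2-fold) and KLK10 (7.72-fold); TGM1 was at least 2-fold higher. Without the filter on dim genes the keratinocyte median was −0.32 and the luminal median −0.11.

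DNA replication genes had a median of 0.06 and 0 of 62 passed 2-fold; GINS4 was 1.95-fold and UHRF1 1.78-fold higher. Mitosis genes had a median of −0.04 and 0 of 44 passed 2-fold, with BUB1 1.68-fold and PTTG1 1.52-fold lower. DNA damage response and repair genes had a median of −0.02 and 0 of 50 passed 2-fold, with MRE11 1.83-fold lower and RAD51C 1.79-fold higher. p53 targets had a median of 0.21, at the 99.6 percentile, with the death receptor TNFRSF10B 2.16-fold higher and CCNG2 2.78-fold lower; CDKN1A was 1.26-fold higher. Cell cycle inhibitors had a median of 0.02, with RB1 1.80-fold higher and RBL2 1.37-fold lower. In the antioxidant list, with a median of 0.10, MSRB3 was 2.83-fold and CAT 2.52-fold higher, and GPX2 53.2-fold and the glutathione synthesis subunit GCLM 2.47-fold lower. MAPK output genes had a median of −0.03, with HBEGF 5.49-fold, LIF 3.05-fold and ITGA2 2.72-fold lower and the phosphatase DUSP1 3.45-fold higher; SPRY2, the other member at least 2-fold higher, was named after its value was seen. Senescence-associated secreted factors had a median of 0.12, with CXCL1 8.49-fold, STC1 7.95-fold and IL6 4.94-fold higher and INHBA 6.34-fold lower. IL1B, also in that list, and MMP10, named after its value was seen, were lower as well, by differences of −1.88 and −1.66. Stem cell associated genes had a median of −0.29 over 13 genes, which was 0.00 without the filter; the pluripotency factor SOX2 was 13.4-fold higher, and ALDH1A3, SOX9 and ABCG2 5.69-fold, 4.79-fold and 2.52-fold lower. Interferon-stimulated genes had a median of −0.37, below each random list and −0.83 on probe sets without a shared-sequence suffix. IFIH1, IFIT2 and MX1 were 4.24-fold, 4.01-fold and 3.33-fold lower, and IFI44L was 13.0-fold higher; BST2, named after its value was seen, was the other member at least 2-fold higher. Glycolysis and hypoxia genes had a median of 0.23, at the 99.9 percentile, with the carbonic anhydrase CA12 4.80-fold, BNIP3L 2.71-fold, the glucose transporter SLC2A3 2.43-fold and ADM 2.12-fold higher. Cholesterol synthesis genes had a median of −0.28, with SQLE 2.18-fold lower. Ribosomal protein genes had a median of 0.01, with RPL34 at 0.16 and RPS15 at 0.15, and the 3 leukocyte and endothelial markers a median of 0.01, with CD14 2.34-fold lower. The count of genes at least 2-fold higher was 308 of 8855 with the median over a gene's probe sets. It was 332 of 9181 without the genes of the chromosome windows beyond the limit described below. Those windows were picked for large medians, partly in this comparison, so leaving them out lowers the count by construction.

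**Figure D2:**
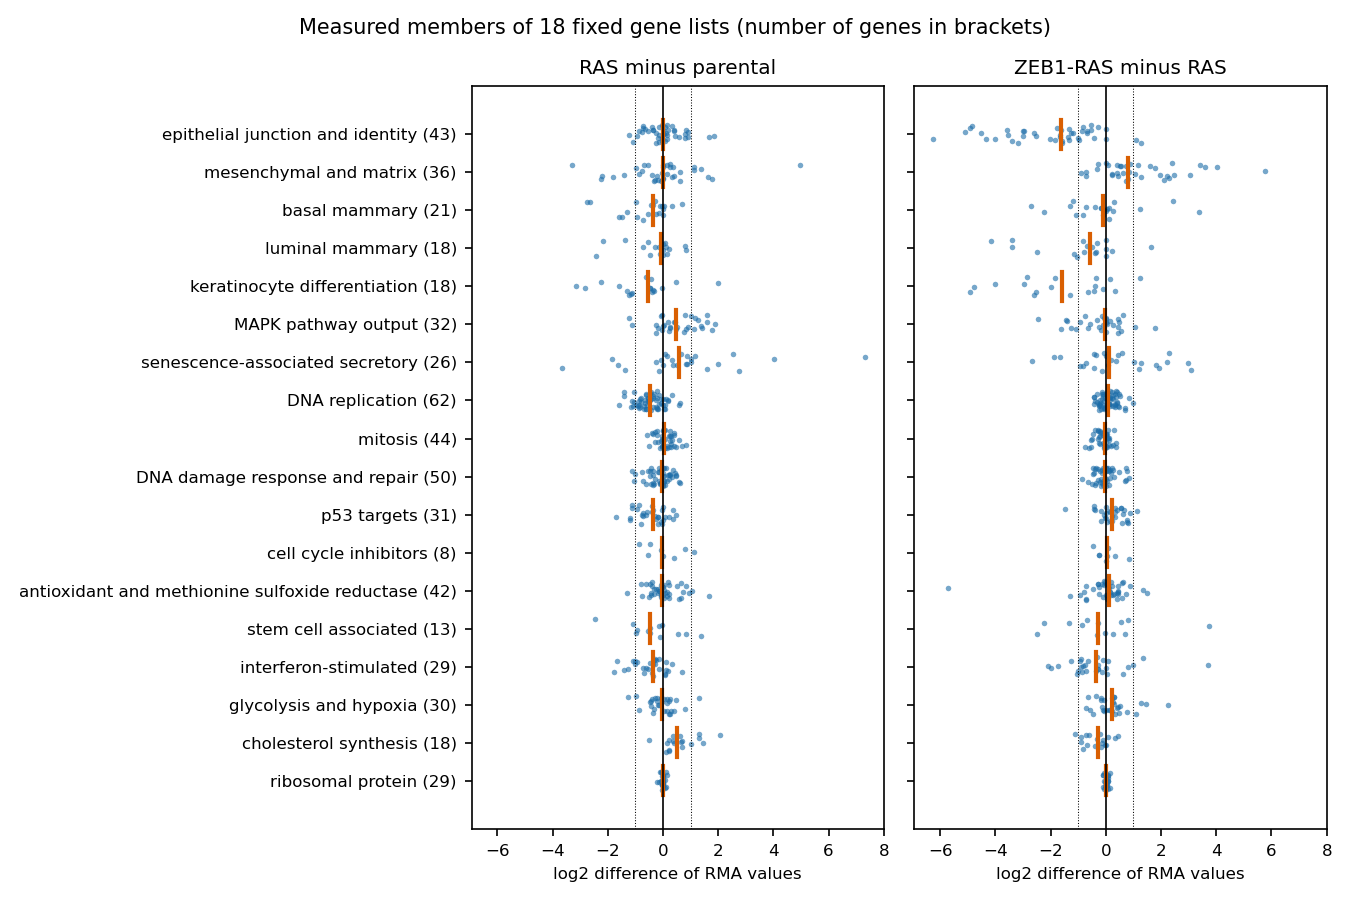
Log2 differences (horizontal axis) of the measured members of 18 fixed gene lists, 1 point per gene and an orange bar at each list's median, for RAS minus parental and ZEB1-RAS minus RAS; dotted lines mark 2-fold. The DNA replication bar lies at −0.48 in the first panel and 0.06 in the second, and the epithelial bar at 0.01 and −1.64.

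The difference of ZEB1-RAS from parental cells is, by arithmetic, the sum of RAS minus parental and ZEB1-RAS minus RAS. Against parental cells, 401 genes were at least 2-fold higher and 644 at least 2-fold lower. RTN1 was 260-fold higher, IL13RA2 93.9-fold, EDIL3 69.3-fold, PRR16 58.8-fold, CLGN 32.1-fold and TMEM100 23.3-fold. The cortisol-activating enzyme HSD11B1 was higher by a log2 difference of 4.70, and NEFL, GRB10, RGS17, the Notch ligand DNER and the Notch target HEY1 by 4.40 to 4.17. RARRES1 was 79.0-fold lower, KRT13 70.3-fold, SPRR1B 42.0-fold, PRRG4 37.4-fold, KRT23 35.4-fold, SCGB1A1 33.9-fold, CLCA4 33.9-fold and ANO1 32.8-fold. LXN, TCN1, CNTN3 and ESRP1 were 32.4-fold to 26.3-fold lower.

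In this comparison, 32 of 43 epithelial genes were at least 2-fold lower and 0 higher, with a median of −1.65; TMEM30B, RAB25 and EPCAM were 25.6-fold, 25.5-fold and 24.2-fold lower, and CDH1 4.62-fold lower. Mesenchymal and matrix genes had a median of 0.68 with 15 of 36 at least 2-fold higher, among them CDH11 (56.6-fold), DCN (20.5-fold), FBN1 (10.6-fold), the protease inhibitor SERPINE2 (10.1-fold) and VIM (6.87-fold). This median ranged from 0.45 without the filter to 1.21 without genes of chromosome windows beyond the shuffled limit. MSRB3 was 4.71-fold higher in an antioxidant list whose median was −0.02; GLRX was 2.55-fold higher, and GPX2 and AKR1B10 16.9-fold and 2.83-fold lower. ME1 and GCLC, named after their values were seen, were the other members past 2-fold, at 1.03 and −1.06. DNA replication genes had a median of −0.35, below each random list, with 54 of 62 genes below 0; the 4 at least 2-fold lower were E2F8 (2.48-fold), the polymerase subunit POLD3 (2.38-fold), MCM5 (2.17-fold) and MCM2 (2.03-fold). Mitosis genes had a median of 0.00, with CDC25B 1.96-fold higher and MKI67 1.36-fold lower. DNA damage response and repair genes had a median of −0.07, and BARD1 was the 1 member at least 2-fold lower (2.31-fold). p53 targets had a median of −0.14, at the 0.97 percentile, with TP53I3 3.61-fold, PLK2 3.08-fold and CCNG2 2.38-fold lower and TNFRSF10A 2.30-fold higher; CDKN1A was 1.47-fold lower. Cell cycle inhibitors had a median of −0.03, with CDKN2B 2.21-fold higher.

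Keratinocyte differentiation genes had a median of −2.22, which was −0.99 on probe sets without a shared-sequence suffix, with 18 of 18 genes below 0 and KLK7 and KLK10 25.4-fold and 23.3-fold lower. Luminal genes had a median of −1.04, with CLDN8 26.3-fold, CD24 11.5-fold, WFDC2 9.38-fold and GATA3 6.60-fold lower and MLPH higher by 1.34. Without the filter, the keratinocyte and luminal medians were −0.85 and −0.10, and the luminal median was −1.65 on probe sets without that suffix. Basal genes had a median of −0.46, with KRT15 18.6-fold, the desmoglein DSG3 4.03-fold, DST 3.51-fold and FGFBP1 2.98-fold lower. Interferon-stimulated genes had a median of −1.01, which was −0.66 with the median over a gene's probe sets, with 15 of 29 at least 2-fold lower, SAMD9 6.43-fold, HERC6 4.61-fold and IFITM1 3.43-fold among them; IFI44L, at 3.84-fold, was the 1 member at least 2-fold higher. MAPK output genes had a median of 0.18, at the 99.7 percentile, with ETV5 4.19-fold and DUSP6 3.75-fold higher and EGR1 5.89-fold, FOS 3.92-fold and HBEGF lower. Senescence-associated secreted factors had a median of 0.75, above each random list, with CXCL5 219-fold, MMP1 9.93-fold and CXCL1 9.45-fold higher and IGFBP3 11.3-fold lower; IGFBP2, named after its value was seen, and INHBA were the other members at least 2-fold lower. Stem cell associated genes had a median of −0.31 and 0.00 without the filter; SOX2 was 6.79-fold higher, PROCR, named after its value was seen, 2.14-fold higher, and ALDH1A1, SOX9, ALDH1A3 and NOTCH1 lower, the first 3 by 10.1-fold, 5.10-fold and 3.21-fold. Glycolysis and hypoxia genes had a median of 0.11, with SLC2A3 4.21-fold, CA12 2.64-fold and BNIP3 2.02-fold higher. Cholesterol synthesis genes had a median of 0.26, which was 0.11 with the median over a gene's probe sets, with SQLE 1.92-fold and INSIG1 1.62-fold higher. Ribosomal protein genes had a median of 0.00, with RPS25 at 0.17 and RPS3 at −0.09, and the leukocyte and endothelial markers one of 0.04, with PECAM1 at 0.20 and CD14 at −0.16.

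The differences of RAS and of ZEB1-RAS from the parental array were set side by side. Both arrays were at least 2-fold above parental for 98 genes, against 10.9 for independent lists, and at least 2-fold below for 216 genes, against 28.1. Opposite directions held for 19 genes higher with RAS and lower with ZEB1-RAS and for 35 genes the other way, against 17.4 and 17.5. With 32 added to the linear intensity, 63 genes were above parental on both arrays, and with the median over a gene's probe sets 61 were above and 135 below. The covariance of the 2 sets of differences across genes, which are not independent replicates, was 0.18, beside 0.01 for simulated unchanged arrays that share the parental array, and r was 0.40 beside a simulated 0.50. The simulation holds only the spread between probe sets, not that between cultures. Because 1 parental array cannot be split, part or all of the excess may come from that shared array. The differences RAS minus parental and ZEB1-RAS minus RAS are called steps here, without implying that the ZEB1-RAS culture came from the RAS culture. In these steps, 191 genes were at least 2-fold lower with RAS than in parental cells and at least 2-fold higher with ZEB1-RAS than with RAS. That count was made after the data were seen, against 22.2 for independent lists, and SELENOP, NID1, GAS1 and PLSCR4 were among these genes. Another 133 genes were higher with RAS and then lower, against 15.3, AKAP12, ANO1, EPCAM and GPX2 among them. Genes differing the same way in both steps numbered 53 lower in both and 24 higher in both, against 24.7 and 13.8. The RAS array enters both steps with opposite signs, which independent lists leave out, so any deviation of that 1 array from its condition adds to the first 2 counts. Across genes, r between the steps was −0.38, beside −0.50 for simulated unchanged arrays. With the offset of 32 and with the median over probe sets, the 191 genes were 113 and 104, and with the offset the 133 were 88.

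**Figure D3:**
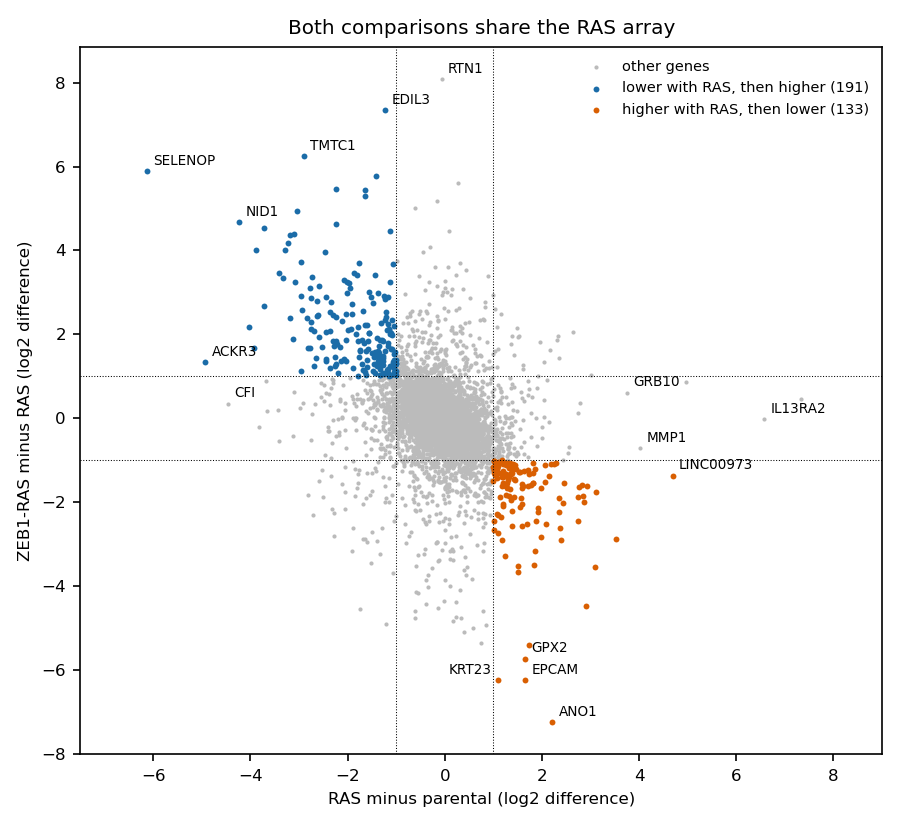
Log2 difference of RAS minus parental (horizontal axis) against that of ZEB1-RAS minus RAS (vertical axis), 1 point per gene, with dotted lines at 2-fold and names for leading genes of both comparisons. The 191 blue genes were lower with RAS and higher with ZEB1-RAS, and the 133 orange genes the reverse; both axes share the RAS array, which tilts the cloud downward by itself.

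Since the series concerns chromosomal instability, differences were also summarised along the chromosomes, outside the fixed design, in 213 windows of 50 to 59 neighbouring measured genes. For RAS minus parental, 15 windows had a median beyond 0.25 in size, the limit set by shuffled gene order, and in 5 of them at least 80% of genes also had 1 sign, as a window counted as a segment shift must: ZNF326 to ELAPOR1 and SARS1 to TRIM45 on chromosome 1, the windows ending at ATP6V1H and starting at RGS20 on chromosome 8, and ZNF443 to AKAP8L on chromosome 19. On chromosome 1, the 3 adjacent windows from SRSF11 to TRIM45 had medians of 0.54, 0.59 and 0.61, and 94.2% of the genes in the last were above 0. On chromosome 8, the windows from PPP3CC to ATP6V1H had medians of −0.43 and −0.61, and the next 3, from RGS20 to FAM83A, 0.43, 0.46 and 0.37. On chromosome 19, the windows from MARCHF2 to AKAP8L had medians of −0.43 and −0.32. For ZEB1-RAS minus parental, 17 windows passed the limit of 0.24, and 2 of them were counted, FBXO25 to SLC39A14 on chromosome 8 and UGGT2 to CHAMP1 on chromosome 13. Of the 17, 3 were shared with RAS minus parental: GLRB to FAT1 on chromosome 4 (−0.30), FAM8A1 to GABBR1 on chromosome 6 (−0.34) and PPP3CC to NRG1 on chromosome 8, where the sign was opposite. On chromosome 8 the windows from FBXO25 to NRG1 were at 0.56 and 0.38, on chromosome 13 the window from UGGT2 to CHAMP1 at 0.53, and on chromosome 11 the windows from ZW10 to GLB1L2 at 0.43 and 0.39. The chromosome 11 windows had 78.4% of genes of 1 sign and were not counted. For ZEB1-RAS minus RAS, 23 windows passed the limit and 11 were counted. Windows beyond the limit without the filter on dim genes numbered 8, 5 and 14 for RAS minus parental, ZEB1-RAS minus parental and ZEB1-RAS minus RAS.

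**Figure D4:**
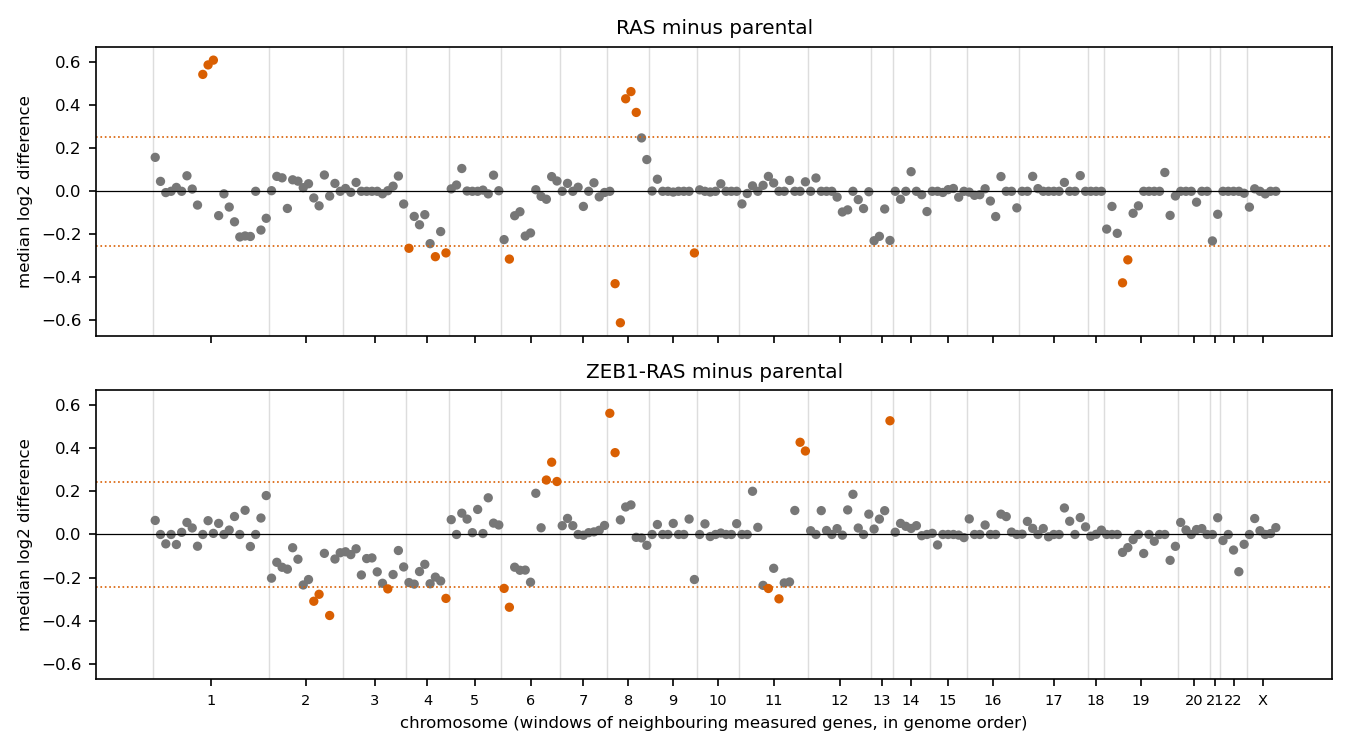
Median log2 difference (vertical axis) of windows of 50 to 59 neighbouring measured genes in genome order (horizontal axis, chromosome names), for RAS minus parental and ZEB1-RAS minus parental; dotted lines are the shuffled-order limits, and windows beyond them are orange. The chromosome 1 group at 0.54 to 0.61 appears with RAS and lies near 0 with ZEB1-RAS, and the chromosome 13 window at 0.53 passes the limit with ZEB1-RAS and not with RAS.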

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

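Probe sets without a single gene name entered no comparison, yet some of them were at least 2-fold above the array used as control. Of 2627 such probe sets, controls aside, that passed the same filter, 49 were at least 2-fold higher for RAS minus parental, 95 for ZEB1-RAS minus RAS and 66 for ZEB1-RAS minus parental. Beside these stand 465, 850 and 622 of the 18610 probe sets with a single gene name, a somewhat higher share in each comparison. The probe sets at least 2-fold lower numbered 93, 123 and 128. They were not followed up here. With 1 array per group, no culture could be compared with others of its group and no difference between group effects was tested.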

How the results depend on the processing

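Alternatives on the windows and turning genes, and those that leave out genes of windows beyond the shuffled limit or with identical values, were chosen after the data were seen. With 1 array per group, no array could be left out and no error exists. A value is therefore said to have moved when it left its main value by more than the probe-set noise, or a count by more than 1.5 times. Causes were not tested, except that a stricter or looser size rule or filter counts fewer or more genes by construction. Leaving out genes of windows picked for large medians also lowers a count by construction. Equal array medians left gene counts, overlaps and window counts within those bounds, and the loess trend these and list medians. Equal medians shift each difference by 0.071 at most, so list medians and single genes could not pass the bound. That bound, the noise of a single gene, is wide for a list median. Of 57 list medians, 30 lay in an outer tail of the random lists (2.5% on either side). None of these 30 changed sign under any setting, although 2 stem cell medians became 0.00; medians close to 0 among the others did change sign, several with equal array medians. Of the 251 named-gene differences, 133 moved with 32 added to the linear intensity, so many fold sizes depend on the offset. With the median over a gene's probe sets 88 moved and 133 did not, and on probe sets without a shared-sequence suffix 14 moved and 173 did not. The loess trend moved 1. Of the named-gene differences of at least 2-fold, none changed sign under these settings, and smaller ones were not checked for a change of sign. No paired analysis was possible because each group has 1 array. Signal over background is a limit at the dim end of the arrays, where fold sizes depend on the offset.

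With the 1.5-fold rule, the counts of higher and lower genes were 804 and 1149 for RAS minus parental, 1121 and 1230 for ZEB1-RAS minus RAS, and 828 and 1325 for ZEB1-RAS minus parental. With the 3-fold rule they were 91 and 203, 256 and 250, and 203 and 315. The median over a gene's probe sets gave 293 lower genes for RAS minus parental and 308 higher genes for ZEB1-RAS minus RAS, with fewer genes tested (8855). Leaving out genes of windows beyond the limit in any comparison gave 332 higher genes for ZEB1-RAS minus RAS among 9181.

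With 32 added to the linear intensity, the ZEB1-RAS minus RAS medians were −1.27 for epithelial, −1.16 for keratinocyte and −0.39 for luminal genes. Those of ZEB1-RAS minus parental were −0.76 for interferon, −1.75 for keratinocyte, −0.70 for luminal and 0.52 for mesenchymal genes.

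With the median over probe sets, RAS minus parental gave 0.26 for MAPK output, 0.25 for mesenchymal, −0.078 for stem cell and 1.07 for leukocyte and endothelial genes (1 gene left). ZEB1-RAS minus RAS gave −1.26 for epithelial and −1.22 for leukocyte and endothelial genes. ZEB1-RAS minus parental gave −1.40 for epithelial, 0.11 for cholesterol, −0.66 for interferon, −1.74 for keratinocyte, −0.16 for leukocyte and endothelial, −0.79 for luminal, 1.08 for mesenchymal and −0.51 for stem cell genes.

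With the filter at 7, leukocyte and endothelial genes (1 left) gave 1.07, −1.22 and −0.16 for RAS minus parental, ZEB1-RAS minus RAS and ZEB1-RAS minus parental. Senescence-associated factors gave 0.35 for RAS minus parental. Keratinocyte genes gave −1.85 for ZEB1-RAS minus RAS and −2.92 for ZEB1-RAS minus parental, luminal genes −0.78 and −1.61, and epithelial genes −1.82 for ZEB1-RAS minus parental.

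With no filter, ZEB1-RAS minus RAS gave −0.32 for keratinocyte, −0.11 for luminal, 0.56 for mesenchymal and 0.00 for stem cell genes. ZEB1-RAS minus parental gave −0.85, −0.10, 0.45 and 0.00 for the same lists and 0.46 for senescence-associated factors, which gave 0.23 for RAS minus parental, where stem cell genes gave −0.028.

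With probe sets free of a shared-sequence suffix, RAS minus parental gave 0.15 for cell cycle inhibitors, −0.33 for keratinocyte, 0.61 for leukocyte and endothelial (2 genes), −0.30 for luminal and 0.85 for senescence-associated genes. ZEB1-RAS minus RAS gave −0.83 for interferon, −0.98 for keratinocyte, −0.58 for leukocyte and endothelial and −0.87 for luminal genes. ZEB1-RAS minus parental gave −0.73 for basal, 0.12 for cell cycle inhibitors, −0.99 for keratinocyte, −1.65 for luminal and 1.19 for senescence-associated genes.

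Without genes of windows beyond the limit, RAS minus parental gave 0.15 for cell cycle inhibitors, 0.84 for senescence-associated and −0.14 for stem cell genes, and ZEB1-RAS minus parental 1.21 for mesenchymal genes. Without genes of identical values, luminal genes gave −1.52 for ZEB1-RAS minus parental.

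Genes at least 2-fold above parental on both arrays numbered 63 with the offset of 32 and 61 with the median over probe sets, and those below on both 135 with the latter. Opposite directions held for 30 and 26 genes under these 2 settings. The covariance was 0.12 without the filter. With the offset, 113 genes were lower with RAS and then higher and 88 the reverse; with the median over probe sets, 104 were lower and then higher. Windows beyond the limit without the filter numbered 8 for RAS minus parental, 14 for ZEB1-RAS minus RAS and 5 for ZEB1-RAS minus parental.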

Other observations

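The tests on fibroblast markers, which took 3 forms in turn, on gene families, on the MAPK list as a check of the RAS label and on an exchange of arrays were chosen after the result was seen. The other methionine sulfoxide reductases, MSRA, MSRB1 and MSRB2, were looked at beside MSRB3 after its values were seen. They differed by −0.26, −0.48 and −0.39 for RAS minus parental and by 0.26, 0.21 and 0.58 for ZEB1-RAS minus RAS, so that, of the 4 reductases, MSRB3 alone was higher on the RAS array than on the parental array. Several genes of the fixed lists were low on the RAS array and near parental on the ZEB1-RAS array. The basal keratin KRT14 read 12.68, 10.05 and 12.49 on the parental, RAS and ZEB1-RAS arrays, KRT5 12.12, 10.52 and 11.74, MME 10.09, 7.35 and 10.71, ZEB2 6.03, 2.73 and 6.74, and CAT 10.68, 9.39 and 10.72.

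Neighbouring genes differed together along several chromosomes, such as the chromosome 1 segment from ZNF326 to TRIM45 with RAS and the chromosome 13 window from UGGT2 to CHAMP1 with ZEB1-RAS. Over the 3 comparisons, which share arrays, 18 windows passed the shuffled limit with at least 80% of genes of 1 sign. A copy-number difference of a segment could give this, but regional control of expression could give the same. Segments that are shorter than a window, split by its borders or weaker than the limit would be missed. Windows that were not counted are thus not shown to be free of such differences. All 7 of these that involve the parental array (100%) stayed beyond the limit without genes differing 2-fold or more. Windows chosen for their median and an 80% share of 1 sign could hardly fail this, so the outcome adds little. The choice itself leaves little room for a few strong genes as the cause. With 1 gene per symbol stem, 85.7% of the 7 stayed beyond the limit. That rule kept 45 to 50 genes per window, and all 50 in the window ending at ATP6V1H. It could therefore move the medians little, and the outcome does not decide about families of neighbouring genes. The chromosome 19 window from ZNF443 to AKAP8L fell inside the limit. Its median went from −0.32 to −0.29 while the limit for the genes kept rose from 0.25 to 0.31, so the shift itself changed little. The same 7 (100%) kept their sign at 0.1 or more on second probe sets, a mark below each of their main medians. This argues against errors of single probe sets. The shuffled limit had already left little room for unrelated errors, so the outcome adds little to it. A candidate explanation is that the cultures differ in copy number of these segments, a hypothesis from RNA alone; regional control of expression and the time at which a difference arose were not tested.

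A set of 191 genes was at least 2-fold lower on the RAS array than on the parental array and at least 2-fold higher on the ZEB1-RAS array than on the RAS array. Of 125 other probe sets of these genes that passed the filter, 92.8% showed both signs. Unrelated errors would give both signs in a minority. For the genes with another passing probe set, this argues against errors of single probe sets. Genes with 1 passing probe set, such as SELENOP, GAS1, PLSCR4, KRT14 and KRT5, were not covered. With the median over a gene's probe sets, the set held 104 genes. Of the 191 genes, 14.7% lay in the 15 windows beyond the limit for RAS minus parental, whatever share of their genes had 1 sign. The share among all placed genes was 6.91%. Differences of these windows could thus account for a minority of the 191 genes at most. Segments that are shorter than a window, split by its borders or weaker than the limit are not counted. The test therefore does not decide how much segment differences of every size contribute. Fewer admixed fibroblasts in the RAS culture were also considered. The test asked whether fibroblast transcripts on the parental array came near the median of the 191 genes, 7.73. COL1A1, COL1A2, COL3A1 and LUM had a median of 4.46 there, at 6.96, 4.75, 4.16 and 2.57. The last 3 lay under the 5.17 of all probe sets. By the rule of the test this speaks against fibroblasts as the source of the whole set. Levels of different probe sets compare only roughly, however, so the test does not decide it. The first form of that test set the same median against fixed levels, with the same outcome and the same limit. The second, the difference of the markers that pass the filter, rested on COL1A1 alone (0.16 for RAS minus parental) and decided nothing. KRT14 and KRT5, keratins of the epithelial cells, are among the 191, but so are members of the mesenchymal and matrix list. Of these, MMP2, COL5A2 and DCN read 8.22, 7.61 and 6.85 on the parental array. An action of ZEB1 against part of the RAS response and a peculiarity of the single RAS culture, such as its density or passage, stay open and were not tested.

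The HRAS probe set was higher by 0.22 on the RAS array than on the parental array, little for an introduced oncogene. An exchange of the RAS and ZEB1-RAS arrays would put ZEB1 on the wrong array, but probe set 212764_at was higher by 5.38 on the ZEB1-RAS array than on the RAS array. The MAPK output list lay at the 100.0 percentile of random lists for RAS minus parental, but 9 of the 19 lists lay in an outer tail there, so this does not decide whether the culture lacks active RAS or has a wrong label of another kind. It also stays open that the probe set may not read the introduced transcript or that the insert is weakly expressed in this culture; neither was tested.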
